A study of Mus musculus with 6 samples.

How the data were processed

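Gene expression was measured in 6 samples of mouse cumulus cells, 3 without hCG (hCG-0h) and 3 after hCG (hCG-6h). Per the labels' protocols, total RNA was extracted with a kit for small samples, amplified to cDNA with a whole-transcriptome kit for very small amounts of RNA, fragmented, labelled with biotin and hybridised, 1 sample to each array. The protocol of RNA extraction speaks of cumulus-oocyte complexes, whereas the growth protocol and the sample names speak of cumulus cells, so oocyte markers were included among the lists below. The handling medium held milrinone, an inhibitor of the phosphodiesterase PDE3 that keeps oocytes from maturing, per the labels' protocols. The deposited values are on the log2 scale, with 2 decimals, for 45101 probe sets. The submitters' processing notes name GCOS, Affymetrix Expression Console 1.1 and RMA, the robust multi-array average, which subtracts background, quantile-normalises the arrays and summarises the probes of a set. RMA background correction pulls dim probe sets toward a floor, which compresses the fold changes of genes that are dim in a group and makes their folds approximate. No detection calls were among the values used here. Median log2 values of the 6 arrays lay between 6.43 and 6.46 and the lowest values between 2.43 and 2.48. A genome build is not given in the sources used here, and no coordinates are printed.

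Probe sets were named from the annotation of the array platform. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed. Entrez gene identifiers of 99.4% of the 1-symbol probe sets (34754) matched the reference gene table, and no symbol needed updating. Only probe sets with 1 symbol were used, and of several probe sets of a gene the one with the highest mean over all 6 arrays was taken, which gave 18194 genes, 9012 of them with more than 1 probe set. Among 2328 called genes with more than 1 probe set, 13 had another probe set past the threshold in the opposite direction, and none of them is among the genes named by the rule below. Other probe sets of a named gene did not always pass, however: 1 of 6 passed for Nr2f2, 1 of 3 for Cyp11a1, 2 of 4 for Ank1 and 3 of 6 for Pde4b. All 6 passed for Runx1 and all 4 for Kctd14. Some members of the gene lists were not analysed here, and of 18 genes fixed by name 15 were measured.

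The comparison of hCG-6h with hCG-0h was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term, all 6 samples, no filter on dim genes). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 18194 genes, with a threshold of 0.05. Log2 changes are hCG-6h minus hCG-0h, given with limma's standard error, and folds are 2 to the power of that change. The median standard error was 0.146, and the median SD within groups was 0.185. Gene lists were tested with camera from limma with its preset correlation of 0.01, two-sided and adjusted over 28 lists, of which 21 are functional and 7 are cell type markers. The lists hold 563 measured genes, 17 of them in more than 1 list. For each list the members that rose or fell were counted after adjustment over all genes and after adjustment over the list alone.

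The named genes follow a rule. They are the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, without predicted genes, small RNA genes and olfactory, vomeronasal and antigen receptor segment genes. To these come up to 4 members of each list, those past the threshold with the largest changes, and the 18 fixed genes. The groups, the main test, the lists, this rule and the other settings were chosen before the data were examined. Any other gene is said in the text to be named after its values were seen.

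The other settings were the sample number as a block, a trend and robust variance, quantile normalisation applied again, centring on array medians, leaving out the dimmest genes by mean level (1 in 3), array weights, the mean of a gene's probe sets, all probe sets on their own, hCG-6h sample 1 alone, each sample left out in turn, and for the lists camera with an estimated correlation, fry and camera on ranks. Where the other fits gave eBayes a trend and robust variance, camera was given a trend alone. A fit with hCG-0h sample 2 alone was added after seeing the data. The scripts were tested on simulated data for the same comparison with 18194 genes, in which 200 genes were changed. Of 50 genes changed by each log2 size, 10% were recovered at 0.5, 74% at 1, and 100% at 2 and at 4, with 4 false among 146 calls. With fewer calls than in the real fit, the adjusted threshold was stricter in the simulation, so these shares may understate recovery. When 1 list was shifted by 1 on the log2 scale, camera called that list and no other. The simulated genes were drawn independently, so this could not test false calls of lists whose genes are correlated.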

Results

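Cumulus cells are the somatic cells that surround the oocyte in an antral follicle. After the ovulatory stimulus they build a hyaluronan-rich matrix and move apart, a process called cumulus expansion. Gene expression was measured in cumulus cells of wild-type mice before and after human chorionic gonadotropin (hCG), the hormone injected to set off ovulation. Female mice aged 21 days received 5 IU of equine chorionic gonadotropin (eCG), which stimulates follicle growth, and 46 h later either received no hCG (the hCG-0h group) or spent 6 h under 5 IU of hCG (the hCG-6h group). Each group held 3 samples, and each sample was made from the cumulus cells of 50 cumulus-oocyte complexes and put on 1 single-colour expression array. The descriptions of hCG-6h samples 2 and 3 give 7 h and 8 h, whereas their titles and source names give 6 h, and all 3 samples were kept as hCG-6h. The labels do not tell whether the samples came from separate animals, so the p-values are set against the spread between these samples, whatever its source. The number of arrays limits the precision of every value. The comparison of hCG-6h with hCG-0h asks which transcripts of cumulus cells differ before and after the ovulatory stimulus. No group without hCG was kept for those 6 h, so effects of hCG and of the longer time cannot be told apart.

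Cumulus cells at hCG-6h differed widely from those at hCG-0h. Of 18194 genes tested, 1968 were higher and 1905 were lower at hCG-6h, together 3873 genes or 21.3% (limma, adjusted p under 0.05). A change of at least 2-fold was seen in 1813 of them, 950 higher and 863 lower. The largest changes were mostly rises, with 99 genes at least 10-fold higher and 30 at least 10-fold lower. The 3 values of one group did not overlap the 3 values of the other in 6901 genes (37.9%, against 10% by chance). Across all genes the median log2 change was 0.0067, which quantile normalisation of the arrays tends to keep small. The first principal component held 74.1% of the variance and placed the hCG-0h samples between -50.64 and -48.85 and the hCG-6h samples between 49.7 and 50.32. Pearson's r across genes, which are not independent replicates, was 0.9819 to 0.985 between samples of one group and 0.9434 to 0.9456 between groups.

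The 10 largest rises among genes whose groups did not overlap ranged from 46.2-fold to 316-fold. At hCG-0h 9 of these 10 genes, all but Ptgs2, lay under 6.08 on the log2 scale, the limit of the dimmest 1 in 3 genes, where background correction compresses folds, so their folds and order are approximate. Nts, which encodes the peptide neurotensin, rose 316-fold, from a log2 level of 4.80 ± 0.44 at hCG-0h to 13.10 ± 0.04 at hCG-6h (SD, n = 3 each). Ptx3, a pentraxin that holds the hyaluronan matrix together, rose 241-fold, from 5.54 ± 0.84 to 13.45 ± 0.03. Sult1e1, the oestrogen sulfotransferase, rose 220-fold and Ereg, the growth factor epiregulin, rose 127-fold (log2 changes 7.78 ± 0.20 and 6.98 ± 0.16, SE). Next came Ptgs2, the inducible prostaglandin synthase, at 74.7-fold, Procr, the protein C receptor, at 70.7-fold, and Sfrp4, a secreted modulator of Wnt signalling, at 68.1-fold. Rnf125, a ubiquitin ligase, rose 56.4-fold, Fabp7, a fatty acid-binding protein, 52.3-fold, and Col4a1, a chain of basement membrane collagen, 46.2-fold. Adjusted p of these 10 genes lay between 9.91e-06 for Nts and 0.000278 for Rnf125.

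Falls were smaller. Kctd14 fell the most, to a level 32.3-fold lower at hCG-6h (log2 change -5.01 ± 0.27, SE, adjusted p = 7.25e-05), followed by Cyp2s1, a cytochrome P450, at 30.7-fold lower. Hpgd, the enzyme that inactivates prostaglandins, dropped from 11.70 ± 0.12 to 7.42 ± 0.28 on the log2 scale (SD, n = 3 each), 19.4-fold lower. Fbp1, an enzyme of gluconeogenesis, was 21.7-fold lower, and Slfn4, a member of the schlafen family, 17.5-fold lower. The other 5 of the 10 largest falls were Cnnm1, Ank1, Rph3al, Tex14 and Fam81a, between 22.3-fold and 24.5-fold lower.

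**Figure D1:**
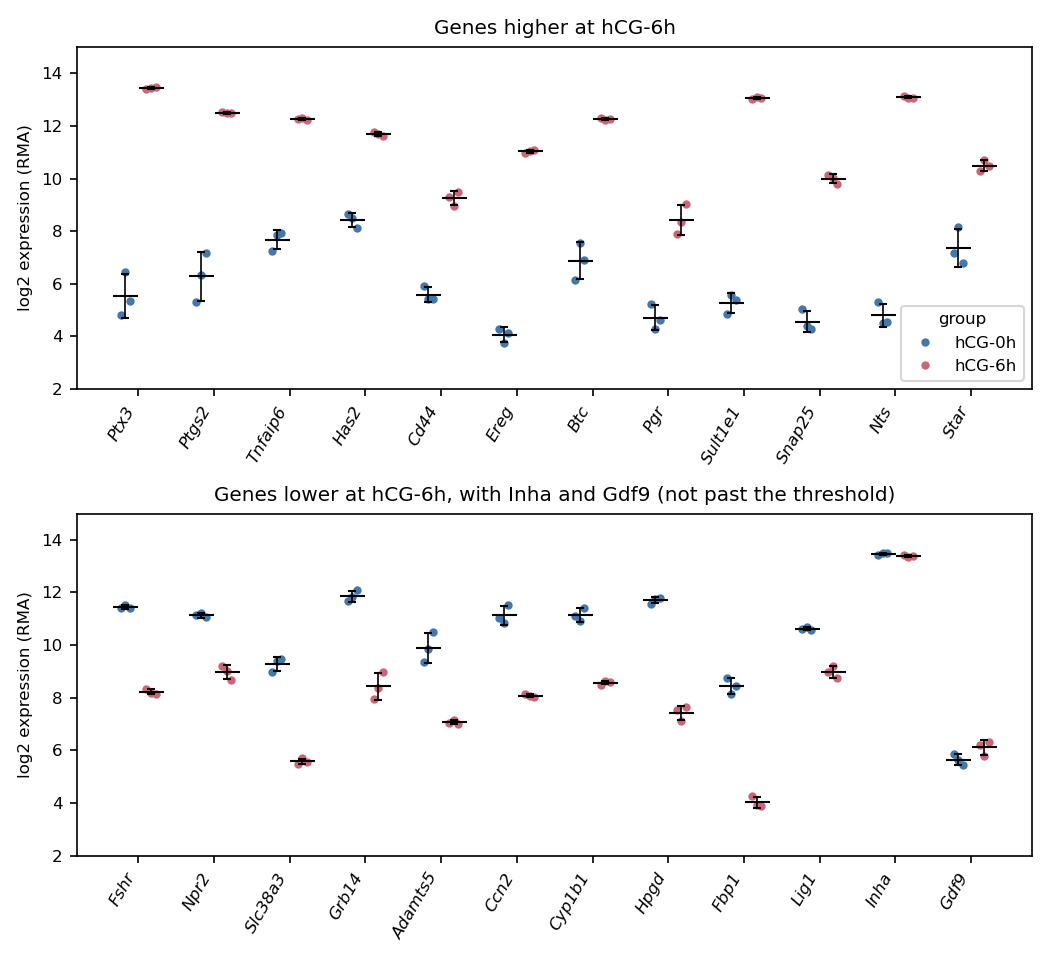
Log2 expression (RMA) of 24 genes in each of the 6 samples, with hCG-0h in blue and hCG-6h in red; dots are samples, and the black lines are the mean and SD of 3 samples. The upper panel holds 12 genes that rose, such as Nts at 4.80 and 13.10; the lower panel holds 10 genes that fell, such as Fshr at 11.45 and 8.23, and Inha and Gdf9, which did not pass the test.

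Most genes of the expansion matrix rose. Of 17 measured members, 12 rose, 1 fell and 4 did not pass (14 rose and 1 fell when adjusted over the list alone), with a median log2 change of 1.75. Tnfaip6, which transfers heavy chains onto hyaluronan, rose 24.0-fold and Has2, the hyaluronan synthase, 9.58-fold (from 8.43 ± 0.27 to 11.69 ± 0.08, SD, n = 3 each). Cd44, the hyaluronan receptor, rose 12.7-fold, beside Ptx3 and Ptgs2. The member that fell was Ptges, a prostaglandin E synthase, with a log2 change of -1.18 (named after its values were seen). The list passed the camera test (adjusted p = 9.1e-09) and missed the threshold there with an estimated correlation (adjusted p = 0.0676).

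Among the EGF-family ligands and receptors, 3 ligands and 1 feedback inhibitor rose. Besides Ereg, Btc, the ligand betacellulin, rose 41.7-fold, Epgn, the ligand epigen, 6.64-fold, and Errfi1, an inhibitor of the EGF receptor, 2.26-fold. Egfr itself was the only member that fell, with a log2 change of -0.71 (named after its values were seen), and 9 of the 14 measured members did not pass. The same 4 and 1 members were counted when adjusted over the list alone. The median log2 change was -0.10 although the mean was 1.02, and the list as a whole did not pass (camera adjusted p = 0.322, direction up).

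Feedback regulators of MAPK signalling and immediate early genes were in part higher at hCG-6h. Of 30 measured members, 17 rose, 2 fell and 11 did not pass, with 20 and 3 when adjusted over the list alone. Dusp6 and Dusp1, phosphatases that switch off MAP kinases, rose 19.6-fold and 8-fold, and the transcription factors Egr3 and Fosl1 rose 7.19-fold and 6.62-fold. Myc and Fosl2 were the members that fell, by 2.39 and 0.65 on the log2 scale (both named after their values were seen). The list passed (camera adjusted p = 7.13e-07; adjusted p = 0.134 with an estimated correlation). In hCG-0h sample 3, all of 12 immediate early genes in this list, singled out after the values were seen, lay lowest among the hCG-0h samples, by a median of -1.22 on the log2 scale. Fos, for instance, stood at 12.17, 12.09 and 10.14 in hCG-0h samples 1, 2 and 3 and at 12.62 to 12.70 at hCG-6h, and it did not pass (adjusted p = 0.163). With each of the samples left out in turn 14 to 19 members of the list rose, with 14 without hCG-6h sample 1 or 3 and 19 without hCG-0h sample 3. Without hCG-0h sample 3 the log2 change of Dusp1 was 2.33 in place of 3.00.

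Transcription factors of ovulation and genes known to depend on the progesterone receptor moved mainly up. In this list of 22 measured members, 15 rose, 4 fell and 3 did not pass, and adjustment over the list alone gave the same counts. Pgr, the progesterone receptor, rose 13.1-fold (from 4.71 ± 0.47 to 8.42 ± 0.57, SD, n = 3 each) and Runx1 rose 6.81-fold. Snap25, a protein of vesicle fusion, rose 43.2-fold, the chemokine receptor gene Cxcr4 38.5-fold and the transcription factor gene Creb3l1 20.4-fold. Those that fell were Nrip1, Nr5a2, Pparg and Fosl2, with log2 changes of -1.69, -1.57, -0.65 and -0.65 (named after their values were seen). The camera test passed (adjusted p = 1.16e-06), and with an estimated correlation it missed the threshold (adjusted p = 0.0676).

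Most genes of follicle growth and of the response to follicle-stimulating hormone fell. Of 25 measured members, 17 fell, 1 rose and 7 did not pass, over all genes and when adjusted over the list alone. Fshr, the receptor of follicle-stimulating hormone, was 9.32-fold lower (from 11.45 ± 0.06 to 8.23 ± 0.10, SD, n = 3 each). Slc38a3, an amino acid transporter of cumulus cells, was 13.0-fold lower, Grb14, an adaptor of receptor tyrosine kinases, 10.8-fold lower, and Npr2, the natriuretic peptide receptor that makes cyclic GMP, 4.48-fold lower. Fgl2 was the member that rose, 7.03-fold. Inha, the inhibin alpha subunit, stayed among the brightest genes, at 13.46 ± 0.05 and 13.39 ± 0.03 (adjusted p = 0.629). Amh, anti-Müllerian hormone, stood at 8.82 ± 0.75 and 7.79 ± 0.46 and did not pass (adjusted p = 0.127), but passed without hCG-0h sample 2 (adjusted p = 0.0275). The list passed as a whole (camera adjusted p = 2.45e-08; adjusted p = 0.0693 with an estimated correlation).

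Steroidogenic genes that changed were mostly higher at hCG-6h. Among 14 measured members of steroidogenesis and cholesterol uptake, 9 rose, 1 fell and 4 did not pass (10 and 1 when adjusted over the list alone). Leaving out each of the 6 samples in turn left 6 to 8 of these members rising and 1 falling. Star, which carries cholesterol into mitochondria, rose 8.73-fold, Cyp11a1, the side-chain cleavage enzyme, 6.59-fold, and Abca1, a cholesterol exporter, 6.62-fold. Cyp1b1, which hydroxylates oestrogens, was 5.94-fold lower. The call held by camera (adjusted p = 0.0011) and was lost with an estimated correlation (adjusted p = 0.0842). Of 19 measured members of cholesterol biosynthesis 7 rose, 2 fell and 10 did not pass, with 8 and 2 when adjusted over the list alone. The largest rises there were those of Msmo1 and Lss, at 1.79-fold and 1.68-fold. With each of the 6 samples left out in turn only 2 to 4 members rose and 0 to 1 fell. That list's call (camera adjusted p = 0.0448) ended without hCG-0h sample 1 or 3 or hCG-6h sample 2 or 3 (adjusted p = 0.0574, 0.115, 0.0506 and 0.113), without dim genes (adjusted p = 0.0828) and with an estimated correlation (adjusted p = 0.548).

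Genes of energy metabolism were mixed. Of 16 measured members of glycolysis, 5 fell and 3 rose, and adjustment over the list alone gave the same counts. Pfkm and Pfkp, phosphofructokinases, were 3.00-fold and 2.26-fold lower, Aldoc, an aldolase, 2.80-fold lower, and Slc16a1, a lactate and pyruvate transporter, 2.19-fold lower. The 3 that rose, named after their values were seen, were Hk1, Hk2 and Slc2a1, which take up and phosphorylate glucose, with log2 changes of 0.83, 0.69 and 0.66. The list did not pass by camera (adjusted p = 0.0838), but passed with a trend in the variance (adjusted p = 0.0112). In the hypoxia-response list 5 of 17 members rose and 3 fell, or 5 and 5 when adjusted over the list alone (camera adjusted p = 0.877), with Ddit4, Egln3, Plin2 and Ndrg1 9-fold, 5.70-fold, 5.64-fold and 3.23-fold higher. Without hCG-0h sample 3 the log2 change of Ddit4 was 2.58 in place of 3.17. The median log2 change of the hypoxia list was slightly below 0 (-0.003) and its mean was 0.34. Of 26 members of oxidative phosphorylation 5 fell and 21 did not pass, also when adjusted over the list alone. The 5 were Sdha, Ndufs3, Atp5c1, Sdhb and Atp5o, the last named after its values were seen. With each of the 6 samples left out in turn, 0 to 1 of these members fell. The list's call (camera adjusted p = 0.0448) ended without hCG-0h sample 2 or 3 or hCG-6h sample 2 or 3 (adjusted p = 0.0756, 0.0828, 0.0559 and 0.0905), with the mean of probe sets (adjusted p = 0.0824), without dim genes (adjusted p = 0.103) and with an estimated correlation (adjusted p = 0.386).

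Genes of DNA replication were in part lower. In the list of S phase and DNA replication, 14 of 28 measured members fell and 14 did not pass, with 16 falling when adjusted over the list alone, and 1 member rose without hCG-0h sample 1. Chaf1b, a histone chaperone subunit, was 3.29-fold lower, the ligase gene Lig1 3.15-fold lower, and the helicase subunit Mcm6 and the polymerase subunit Pola1 each 2.89-fold lower. The list passed (camera adjusted p = 7.13e-07; adjusted p = 0.0693 with an estimated correlation). Of 31 mitotic genes, 7 fell, 2 rose and 22 did not pass, with 11 and 2 when adjusted over the list alone. Ccnb2, a B-type cyclin, was 2.29-fold lower and Bub1b, a spindle checkpoint kinase, 1.96-fold lower, whereas the mitotic kinase Plk1 rose 1.86-fold. With each of the 6 samples left out in turn 4 to 5 of the mitotic genes fell and 1 to 2 rose, and the call of that list (camera adjusted p = 0.0229) ended without hCG-0h sample 2 (adjusted p = 0.0589), without dim genes (adjusted p = 0.0651) and with an estimated correlation (adjusted p = 0.275). Cell cycle inhibitors and p53 targets went both ways, with 8 of 20 rising and 4 falling, or 10 and 5 when adjusted over the list alone (camera adjusted p = 0.123). Gadd45b rose 4.53-fold, Cdkn2d, an inhibitor of cyclin-dependent kinases, 4.15-fold and Zmat3 3.28-fold. With each sample left out in turn 5 to 8 of these genes rose and 2 to 3 fell.

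Inflammatory genes were in part higher. Of 32 measured members of the innate immune and inflammatory list, 12 rose, 2 fell and 18 did not pass, with 13 and 3 when adjusted over the list alone. Il6, the cytokine interleukin-6, rose from a log2 level of 2.98 ± 0.06, near the floor of the arrays, to 6.38 ± 0.25 (SD, n = 3 each). The interleukin-1 receptor gene Il1r1 rose 3.87-fold, Socs3, a feedback inhibitor of cytokine signalling, 3.72-fold, and the chemokine gene Cxcl2, dim in both groups, from 3.78 to 5.38 on the log2 scale. The members that fell were Cd200 and Irf1, 2.86-fold and 2-fold lower (named after their values were seen). With each of the 6 samples left out in turn 7 to 11 members rose and 1 to 2 fell, with the 7 without hCG-6h sample 3. The call by camera (adjusted p = 0.0212) ended without dim genes (adjusted p = 0.182) and with an estimated correlation (adjusted p = 0.134). Regulated secretion and neuronal-type genes showed a few large rises, with 7 of 21 measured members rising, 1 falling and 13 not passing, also when adjusted over the list alone. Beside Nts and Snap25, the peptide gene Gal rose 5.40-fold and Chgb, a secretory granule protein, 4.98-fold, and the member that fell was Unc13b, with a log2 change of -0.73 (named after its values were seen). That fall was not called without hCG-0h sample 2. This list passed by camera (adjusted p = 0.00751), not with an estimated correlation (adjusted p = 0.309).

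Proteases and their inhibitors mostly rose where they changed. Of 20 measured proteases and protease inhibitors, 10 rose, 1 fell and 9 did not pass (11 and 1 when adjusted over the list alone). Leaving out each sample in turn left 7 to 9 rising, and without hCG-6h sample 2, 2 fell. Plaur, the urokinase receptor, rose 22.6-fold, the inhibitor Timp1 11.4-fold and the membrane protease Mmp14 4.62-fold, while Adamts5, a protease that cuts proteoglycans, was 7.06-fold lower. The list passed (camera adjusted p = 0.000404; adjusted p = 0.0718 with an estimated correlation). In the list of gap junctions and cell adhesion, 8 of 29 rose, 3 fell and 18 did not pass, with 11 and 3 when adjusted over the list alone. Those with the largest changes were matrix proteins and a matrix receptor, namely Col4a1, Col4a2 at 19.2-fold, the fibronectin receptor subunit Itga5 at 17.8-fold and fibronectin itself, Fn1, at 4.16-fold. With each of the 6 samples left out in turn 1 to 2 members fell. Gja1, the main connexin between cumulus cells, had a log2 change of -0.12 and did not pass (named after its values were seen). That list's call (camera adjusted p = 0.0466) ended without hCG-0h sample 1 or hCG-6h sample 1 or 3 (adjusted p = 0.0574, 0.0519 and 0.113), with array weights (adjusted p = 0.0541), with the mean of probe sets (adjusted p = 0.0882), on ranks (adjusted p = 0.123) and with an estimated correlation (adjusted p = 0.261).

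Targets of TGF-beta, activin and BMP signalling changed in both directions. Of 22 measured members, 7 rose, 3 fell and 12 did not pass, with 10 and 3 when adjusted over the list alone. The inhibitor of differentiation genes Id1, Id4 and Id3, targets of BMP signalling, rose 5.63-fold, 4.45-fold and 3.71-fold, while Ccn2, a target of TGF-beta, was 8.36-fold lower. Without hCG-0h sample 2 or 3, or any 1 of the hCG-6h samples, only 1 member fell. The list passed by camera (adjusted p = 0.011) and not with an estimated correlation (adjusted p = 0.275). Genes of cyclic AMP and cyclic GMP signalling also went both ways, with 5 of 24 rising and 6 falling, or 6 and 6 when adjusted over the list alone, and that list did not pass (camera adjusted p = 0.852). Prkg2, a cyclic GMP-dependent kinase, rose 12.4-fold and the cyclic AMP phosphodiesterases Pde4b and Pde4d 12.2-fold and 6.23-fold, whereas Npr2 fell.

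Few genes of protein folding and synthesis changed. In the list of endoplasmic reticulum stress, Edem1 and Hyou1 rose, by 1.83-fold and 1.28-fold, and 20 of 22 members did not pass, with 1 rising when adjusted over the list alone (camera adjusted p = 0.731). Hyou1 lost its call whichever of the 6 samples was left out (adjusted p from 0.07 to 0.115). Of 19 measured cytosolic ribosomal protein genes, Rpl14 rose 1.64-fold and 18 did not pass, and none passed when adjusted over the list alone (camera adjusted p = 0.488). The call of Rpl14 was lost with 5 of the 6 samples left out in turn (adjusted p up to 0.0797). The ribosomal list passed, with direction down, when the variance was given a trend (adjusted p = 0.00762) and by fry (adjusted p = 0.0434).

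None of the 7 lists of cell type markers passed by camera, while by fry those of theca and stroma and of mural granulosa cells did (adjusted p = 0.0031 and 0.0401). Of 29 measured oocyte markers, 28 did not pass and Ooep rose 3.82-fold, from 6.53 ± 0.33 to 8.47 ± 0.13 (SD, n = 3 each, camera adjusted p for the list 0.708), and 2 oocyte markers rose without hCG-0h sample 2. The oocyte genes Gdf9 and Zp3 stood at 5.65 and 4.68 at hCG-0h and at 6.11 and 4.85 at hCG-6h (adjusted p = 0.123 and 0.342). Of the 29 oocyte markers only 2 lay above the median level of all genes at hCG-0h, and their mean level was 5.61. These low levels argue against a large share of oocyte RNA in the samples. Of 7 mural granulosa markers, 3 of which are also in other lists, Cyp11a1, Cd34 and Nrp2 rose 6.59-fold, 6.56-fold and 3.47-fold, while Gpr165 was 2.58-fold lower and Nppc and Mgarp fell by 1.31 and 1.14 on the log2 scale, these last named after their values were seen (camera adjusted p = 0.852). In the theca and stroma list of 19, Hpgd, Aldh1a1 and Ptch1 fell and Nr2f2 rose 1.37-fold (camera adjusted p = 0.482); Hpgd was among the bright genes of these cumulus samples before hCG. Nr2f2 lost its call without hCG-0h sample 2 or hCG-6h sample 3 (adjusted p up to 0.0599). By limma 0 of 15 endothelial markers passed (camera adjusted p = 0.708), and 0 of 15 markers of ovarian surface and oviduct epithelium (camera adjusted p = 0.852), while 3 of each had an unadjusted p under 0.05. When each sample was left out in turn, 0 to 1 endothelial marker rose and 0 to 1 fell, 0 to 1 epithelial marker fell, and 1 to 2 leukocyte markers rose. At hCG-0h only 1 endothelial, 1 leukocyte and 2 epithelial markers lay above the median level of all genes (7.22). Markers this dim leave little room to see a fall, so these 3 lists say little about changes in cell composition. Of 20 leukocyte markers Fcgr3 rose 1.68-fold and Fcer1g was 1.84-fold lower (camera adjusted p = 0.574), the latter with its call lost in 5 of the 6 fits that left out a sample. Of 8 erythroid markers, the globin gene Hbb-b2 rose 7.67-fold while Klf1 and Alas2 were 5.23-fold and 2.54-fold lower (camera adjusted p = 0.852). Adjusted over the list alone, the counts of these 7 lists were the same, except that no leukocyte marker fell. The median log2 change of the theca and stroma list was 0.003 against a mean of -0.39 and direction down, that of the erythroid list 0.07 against -0.06 and down, and that of the epithelium list 0.007 against -0.03 and up.

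**Figure D2:**
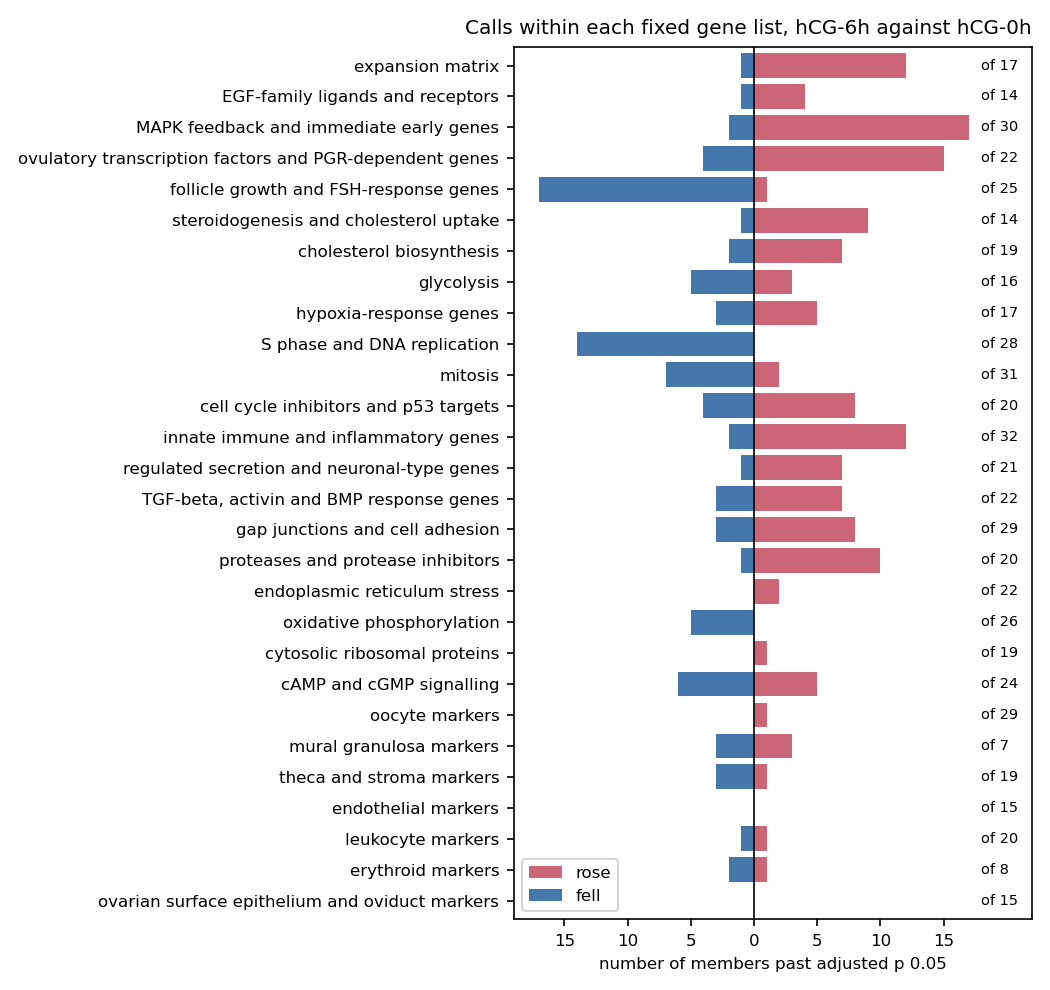
Number of members of each of the 28 fixed gene lists that rose (red, to the right of 0) or fell (blue, to the left of 0) at hCG-6h with adjusted p under 0.05, with the number measured at the right. The expansion matrix list shows 12 rises of 17 members and the follicle growth list 17 falls of 25.

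By camera, 14 of the 28 lists passed. With an estimated correlation between genes 0 did, the lowest adjusted p being 0.0676, and 8 lists had an unadjusted p under 0.05. That setting also takes its degrees of freedom from the 6 arrays instead of the number of genes. The ovulatory, steroidogenesis and protease lists lost their calls with estimated correlations of -0.0197, -0.0482 and -0.0323, under the preset of 0.01. Their loss is therefore no evidence of stronger correlation between their genes. In fry, which tests each list on its own without setting it against other genes, 21 lists passed.

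Individual hCG-0h samples differed from each other in a few sets of genes that the groups do not explain. Transcripts made by the liver, noticed in the values, were high in hCG-0h sample 1, where Alb, serum albumin, stood at 10.38 against 6.25 and 6.00 in hCG-0h samples 2 and 3 and 6.01 to 6.17 at hCG-6h. Alb did not pass between the groups (adjusted p = 0.423). Limma's array weights gave hCG-0h sample 1 the lowest weight, 0.609, against 0.985 to 1.223 for the others. Without hCG-0h sample 1 and without hCG-0h sample 3, 3210 and 2962 genes passed, and 2950 and 2797 of these were among the 3873.

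**Figure D3:**
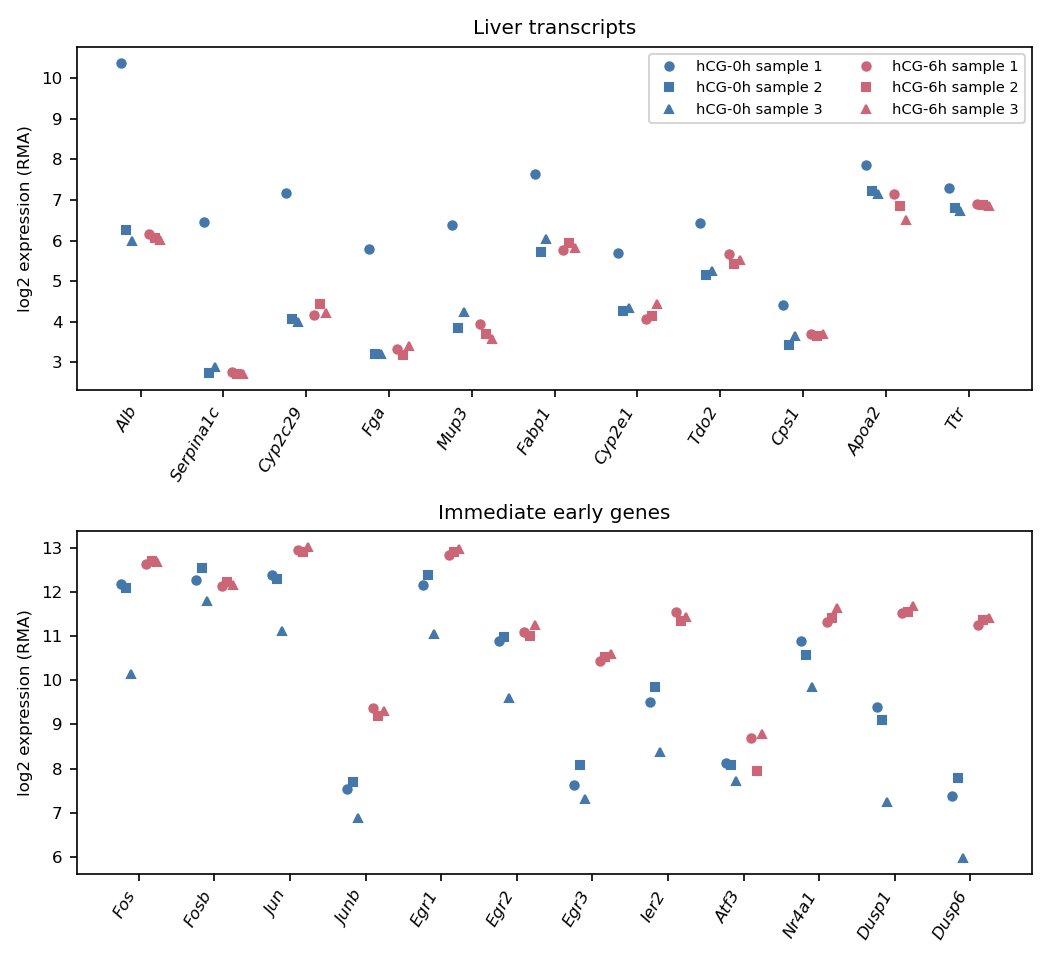
Log2 expression (RMA) of 11 liver transcripts (upper panel; 5 noticed in the values and 6 picked for the plot from a tested list of 19) and 12 immediate early genes singled out after the values were seen (lower panel), in each sample; colours give the group and symbols the sample number. Alb stands at 10.38 in hCG-0h sample 1 against 6.25 and 6.00 in the other hCG-0h samples, and Fos at 10.14 in hCG-0h sample 3 against 12.17 and 12.09. The 6 picked transcripts all come from the 12 of the 19 that were highest in hCG-0h sample 1. The plot leaves out those of the 19 that were not.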

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

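The probe sets described here were set aside by the naming rule before the data were examined, and all of them were tested in a fit of all probe sets of the arrays, each on its own. Signals outside the named genes were found in probe sets that the annotation does not pair with exactly 1 gene. Of 9160 probe sets without a listed gene, control probe sets left out, 285 were higher and 420 lower at hCG-6h than at hCG-0h (limma, adjusted p under 0.05). At least 4-fold changes were seen in 58 that were higher and 49 that were lower. Of 932 probe sets listed with several genes, 71 were higher and 41 lower at hCG-6h. These probe sets were not analysed here as genes.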

How the results depend on the processing

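The fit with hCG-0h sample 2 alone was chosen after seeing the data, and the other settings were planned. No named gene changed direction in the settings that tested it; 5 of 111 were left out with the dim genes, and single genes were not followed with all probe sets on their own. More genes were higher than lower in most settings, but fewer without hCG-6h sample 1 (1475 higher, 1484 lower) and with all probe sets on their own, and without hCG-0h sample 1 the counts were equal (1605 each). RMA had already quantile-normalised the arrays, so quantile normalisation applied again and median centring could change little. The number of genes past the threshold (3873) lay between 3828 and 4274 with a trend and robust variance, repeated quantile normalisation, median centring, array weights, the mean of probe sets or without dim genes. With one sample left out at a time it lay between 2919 and 3210, with 1475 to 1605 higher, 1402 to 1605 lower and 1693 to 1748 changed at least 2-fold. When all probe sets were tested on their own, 6928 probe sets passed, 3390 higher, 3538 lower and 3735 at least 2-fold, since more features were tested. Against the 3 hCG-0h samples, hCG-6h sample 1 alone gave 1576 genes, 809 higher and 767 lower, and against the 3 hCG-6h samples, hCG-0h sample 2 alone gave 1645 genes, 889 higher and 756 lower, with the lone sample assumed to vary like the other group. These fits rest on 4 samples. The sample numbers share only a number: correlations of same-numbered deviations from the group means were 0.012, -0.016 and 0.029, and of all 9 correlations the lowest was -0.035. By these correlations not every sample was closest to the one with its own number. A fit with the number as a replicate block gave 3264 genes, of which 3047 were among the 3873, and 12 lists, without those of cholesterol biosynthesis (adjusted p = 0.0693) and oxidative phosphorylation (adjusted p = 0.0804). In that fit 7 of the named genes lost their call and Amh gained one (adjusted p = 0.0163). Of 28 lists, 10 to 16 passed by camera in the other settings that keep its preset correlation, 13 on ranks and 21 by fry, and 0 with an estimated correlation. Of 111 named genes, 2 lost their call with the mean of probe sets, 7 to 10 with a sample left out, 22 with hCG-0h sample 2 alone and 27 with hCG-6h sample 1 alone; Amh also gained one without hCG-0h sample 2 (log2 change -1.44). Dim signal limits the values too: the dimmest 1 in 3 genes had a mean log2 level under 6.08. Changes of 0.5 on the log2 scale were recovered in 10% of simulated cases. The simulation made 146 calls against 3873 in the real fit, so its adjusted threshold was stricter and the 10% may understate real recovery.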

Other observations

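The gene groups of the first 2 paragraphs, and the tests of a mislabelled sample, of progress along the hCG response and of oocyte RNA, were chosen only after the results were seen; the tests of other liver transcripts, of other rapidly induced genes and of sample splits were fixed before theirs were seen. Cytokines of the interleukin-6 family and their receptors, drawn up as a list of 14 genes after the values were seen, rose in 6 of 11 measured members, and none fell. Clcf1, a cytokine of this family, rose 29.2-fold, from a log2 level of 6.35 ± 0.17 to 11.22 ± 0.18 (SD, n = 3 each), and Osmr, the oncostatin M receptor, 9.94-fold. Il6 rose from near the floor of the arrays, and Lif, Il11 and Il6ra rose with log2 changes of 1.31, 1.06 and 1.05. Il6st, the receptor subunit shared by the family, and Lifr had log2 changes of -0.29 and -0.31 and did not pass. The median log2 change was 1.05 (camera adjusted p = 0.00127 over these 2 later lists; adjusted p = 0.0504 with an estimated correlation). Of the 11, 4 are also in the fixed lists, and a list drawn up from genes seen to rise is no independent evidence of its direction.

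Genes of retinoid metabolism and transport, a second list of 20 genes drawn up after the values were seen, went both ways. Of 18 measured members 3 rose and 4 fell, and the list did not pass (camera adjusted p = 0.47). Among enzymes that make retinoic acid, Aldh1a3 rose (log2 change 3.46 ± 0.18, SE), Aldh1a1 was 4.47-fold lower and Aldh1a2 did not pass (log2 change 0.003, limma adjusted p = 0.989). Aldh1a7, a close relative of Aldh1a1, was 11.2-fold lower. Rdh10, which oxidises retinol, rose 5.23-fold, and Dhrs3, which reduces retinal back to retinol, was 12.9-fold lower. Stra6, a receptor for retinol uptake, was 7.23-fold lower, and Rbp4, the retinol carrier, rose 3.22-fold.

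Liver transcripts were high in hCG-0h sample 1. The 5 noticed first (Alb, Serpina1c, Cyp2c29, Fga and Mup3) exceeded the mean of the other hCG-0h samples by a median of 3.14 on the log2 scale, and 19 further liver transcripts did so by a median of 0.565, above 100% of 10000 random lists matched on mean level, with 12 of the 19 highest in that sample among all 6. Only 2 of those 19 lay above the median level of all genes in the other 5 samples, and none is in a fixed list. A swap of sample 1 with an hCG-6h sample is argued against by the first principal component. There sample 1 lay 1.70% of the way from the other hCG-0h samples to the hCG-6h samples. Alb stood at only 6.01 to 6.17 in the hCG-6h samples, so such a swap would not bring in liver transcripts. That component separates the 2 groups and does not address other mix-ups of samples. Liver RNA in this sample stays a candidate explanation, although the rises over the next highest sample were uneven, at 4.13 for Alb, 1.61 for Fabp1, 1.25 for Cyp2e1, 0.64 for Apoa2 and 0.38 for Ttr. Those of the 19 that were not highest in sample 1 lay under another sample, such as Ahsg at -0.22, Bhmt at -0.46 and Gnmt at -0.65. No biological explanation was tested.

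Immediate early genes were lower in hCG-0h sample 3 than in the other hCG-0h samples, by a median of -1.22 on the log2 scale over 12 genes. Other genes that rise after hCG showed no such shift: 319 genes at least 4-fold higher at hCG-6h differed in sample 3 by a median of -0.015, with quartiles of -0.31 and 0.34. Genes that start to rise later, or that were dim before hCG, need not show an early difference. Of the 10 largest rises, 9 lay under 6.08 at hCG-0h. By the labels no hCG-0h sample received hCG, so sample 3 could not be less far along an hCG response. Whether a sample departed from its labels in this, the 319 genes cannot decide. Over 20 other rapidly induced genes, 1 of which is in a fixed list, the median was -0.58, below 100% of 10000 random lists matched on mean level, and 19 of them were lower in sample 3 than in the other hCG-0h samples. A difference in handling or in time to lysis, which would move rapidly induced genes at large, may therefore lie behind it, and neither is given in the labels. The 12 immediate early genes had a median log2 change of 1.12 at hCG-6h with 6 of them rising, and without sample 3 a median of 0.68 with 9 rising.

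Ooep, an oocyte gene, was higher at hCG-6h by 1.93 on the log2 scale. More oocyte RNA at hCG-6h as the whole cause is argued against by the 9 other oocyte markers that lay above 6.08 at hCG-0h, whose median log2 change was -0.01 with quartiles of -0.31 and 0.10 and of which 0 passed by limma (3 had an unadjusted p under 0.05). All 28 other markers, most of them dim, had a median log2 change of 0.020 with quartiles of -0.05 and 0.13. Among the 9, Dppa3, named after its values were seen, had a log2 change of 0.96 (adjusted p = 0.0851). Expression of Ooep in cumulus cells after hCG and a probe set that reads another transcript may both account for it, and neither was tested.

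The 10 splits of the 6 samples, the real one included, are too few for a share under 0.05. The real split gave 3873 genes and the highest other split 0; 14 lists passed in the real split and 9 in the highest other one, that of hCG-0h samples 1 and 3 with hCG-6h sample 1 against the rest. In both tests 1 of the 10 splits, the real one, gave as many. Every other split mixes samples of both groups on each side. The difference between the groups thus widens the spread within its sides and still enters its contrast. The counts of the other splits, 0 genes and up to 9 lists, therefore do not measure what arises without a group difference.

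Differences between 3' and 5' control probe sets, a measure of RNA quality and amplification, were 0.35 ± 0.04 at hCG-0h and 0.42 ± 0.07 at hCG-6h for Gapdh and -0.55 ± 0.02 and -0.61 ± 0.05 for Actb on the log2 scale (SD, n = 3 each). Exact two-sided permutation tests gave p = 0.2 and p = 0.3, where 0.1 is the smallest p that 3 against 3 allows.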
